A study of Mus musculus with 4 samples.

How the data were processed

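Gene expression was compared between cultures from APPswe/PS1dE9 mice, which carry transgenes of familial Alzheimer's disease, and cultures from wild-type (WT) mice. Per the labels, neural precursor cells came from the telencephalon of C57BL/6 embryos at day 13, grew as neurospheres for 5 days with EGF and FGF2, and were then plated without these growth factors for 7 days. From each culture, 100 ng of total RNA was amplified and labelled. Each of 4 Agilent arrays carried 1 APPswe/PS1dE9 RNA and 1 WT RNA. APPswe/PS1dE9 was in Cy3 on replicates 1 and 2 and in Cy5 on replicates 3 and 4. The series design names 4 biological replicates per genotype. It does not say whether they came from separate animals or litters, so p-values measure the spread between these arrays, within a dye orientation.

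Per the file headers, the arrays lay on 1 slide with 1 scan and were read with Feature Extraction 11.0.1.1, and the array annotation uses mm9. The authors deposited scanner files with median intensity values of each spot and its local background in both channels, not normalized. The same deposited files hold processed intensity values, which are background-subtracted and dye-normalized per the file headers, and their log10 ratio of Cy5 over Cy3. A deposited value table for 29350 spots states no scale, centring or direction. Set against the scanner files, the values the authors deposited there were log2 ratios of the processed signals with no centring, running APPswe/PS1dE9 over WT, with slopes of -1.00, -1.00, 1.00 and 1.00 on log2 Cy5/Cy3. The column medians in that deposited table were -0.0797, -0.155, -0.0373 and -0.0378. Its spots were the 29350 spots that passed the filter described next.

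The design fixed before the data were examined named mean foreground signals. The files hold median foreground signals, and these were used. Background was corrected by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3), and loess was run within each array with control spots and outlier spots at weight 0. Control spots and outlier spots were then left out, and spots of a probe were averaged. A probe was kept if it was well above background in the channel of 1 genotype on at least 3 of the 4 arrays, which left 26912 of 55681 probes. By accession, 27509 probes matched 20887 symbols in a RefSeq table of assembly GRCm38.p6, which was used for names alone because its build differs. A gene with several kept probes was represented by the probe of highest mean intensity. Of 454 genes past the threshold with several kept probes, 26 had a probe of the opposite sign, and none of those probes passed the test. This gave 20591 features, of which 13664 were named genes.

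The log2 ratios were fitted with limma lmFit and eBayes, with a genotype coefficient and a dye intercept, on 2 residual and 4.13 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all features, at a threshold of 0.05. Values are fitted log2 ratios of APPswe/PS1dE9 over WT ± SE (n = 4 arrays). A difference in the genotype ratio between the 2 dye orientations, from dye or not, goes into the dye intercept. SE and p-values leave it out and cover the spread between arrays of the same orientation. Cxcl5, for example, was at 1.94 and 2.17 on replicates 1 and 2 and at 2.75 and 3.19 on replicates 3 and 4, with an SE of 0.09. The dye term passed the threshold after adjustment in 0 features, which does not show that the 2 orientations agreed. Across features, Spearman correlations of the genotype ratios were 0.55 and 0.49 between arrays of the same orientation. Between arrays of different orientation they were 0.11 to 0.27. The offset draws the ratios of dim spots towards 0. Where the WT channel was not well above background on any array, this is said. A fold was then also computed per channel after loess and Aquantile, against the higher of the lowest signal well above background and the spot's own. It carries no SE and sets no lower limit, and for Ccl4 and Flt1 it equalled the fitted fold. The number of arrays limits the precision.

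The 29 gene lists were fixed before the data were examined, and the 27 with at least 3 measured genes were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. List medians cover the measured genes, while the set tests and their alternatives use genes with values on all arrays. With an estimated correlation, camera takes p from the 2 residual degrees of freedom of the arrays, and with the preset correlation it does not. fry tests whether the genes of a list move one way on balance and does not set them against other genes. Named genes were the 12 highest and 12 lowest log2 ratios among named genes past the threshold with 1 sign on all 4 arrays; App and Prnp; the 4 members of smallest p, in the direction of the list, of each list past the threshold; and Gfap, Aif1, Tubb3, Mbp, Nes and Mki67. Other members of the lists are named as examples chosen after their values were seen. Some items that these rules cover are not reported here.

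The fit and the set test were run on 20 simulated data sets of 20506 genes for this comparison, 200 of them changed. Independent log2 ratios were simulated, so background correction, loess, the filter and the probe rule were not tested. Genes of a list are correlated in the data (estimated correlation up to 0.79, for proliferation), so these rates may not carry over. With variances drawn from the fitted prior, changes of 0.5, 1, 2 and 4 on the log2 scale were called in 55.3%, 96.4%, 99.8% and 100% of genes, and 4.4% of calls were false. With each gene's moderated variance taken as its true variance, 93.6% of changes of 0.5 were called and 9.7% of calls were false, above the nominal 5%. Alternatives covered the dye term, background correction, normalization, source of the values, filter, probe rule, variance model, array weights, set test and leaving out each array. On the 2 same-sex arrays, 1 per dye orientation, a dye intercept leaves no residual degree of freedom, so the genotype coefficient alone was fitted there. Figures were drawn with matplotlib 3.10.9.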

Results

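RNA of differentiated neurosphere cultures from APPswe/PS1dE9 and WT embryos was measured on 4 two-colour arrays, each pairing 1 culture of either genotype, with the dyes exchanged on 2 of the arrays. Between 47.5% and 59.6% of the 59305 probe spots of an array were well above background in a channel, and no spot was saturated. The comparison asked which genes, and which groups of immune, glial and neuronal genes, differed between cultures of a familial Alzheimer's disease model and WT cultures.

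The 12 largest increases among named genes in APPswe/PS1dE9 cultures included interferon-induced, complement, chemokine and leukocyte genes. Cxcl10, a chemokine induced by interferons, was 22.6-fold higher (log2 ratio 4.50 ± 0.11), and complement component C3 was 18.0-fold higher (4.17 ± 0.11), with its second probe at 3.13. The interferon-induced genes Rtp4 (3.12 ± 0.12), Oasl2 (3.05 ± 0.13) and Gbp3 (2.46 ± 0.10) followed. So did the leukocyte genes Cd52 (2.60 ± 0.07), Ctss (2.52 ± 0.07) and Cx3cr1 (2.31 ± 0.08, with another probe at 1.04). The lysozyme gene Lyz1 was at 2.63 ± 0.15, while the lysozyme gene Lyz2, not among the 12, was at 0.84 ± 0.13. The chemokine genes Cxcl5 (2.51 ± 0.09) and Ccl2 (2.40 ± 0.09) completed the 12 highest together with Ccl4 (2.46 ± 0.07, 5.49-fold). The WT signal of Ccl4 was not well above background on any array, and Feature Extraction's processed signals, described below, put Ccl4 at 5.25. Each of these 12 was higher on 4 of 4 arrays, with adjusted p between 7.20e-05 and 0.000393. In all, 1698 features were higher and 470 lower among 20591 tested, and 204 of those higher and 1 of those lower differed by at least 2-fold. The higher share of these calls, 78.3%, depended on the scaling, since median centring without loess gave 1308 higher and 1307 lower. Without replicate 3 the counts were 517 and 29, without replicate 4 they were 368 and 4, and on the 2 arrays where Xist was well above background in both cultures and the Y-linked gene Eif2s3y in neither, called same-sex arrays here and chosen after seeing the data, they were 469 and 11 in a fit of the genotype coefficient alone, which 2 arrays allow. With Feature Extraction's own processed signals, which carry no offset, the counts were 719 and 240, and 23 named genes differed by over 1.5 times more. On the log2 scale Oasl2 was then at 3.83 and Rtp4 at 3.81, and Lyz1 was at 3.99, Cd52 at 3.81 and Cx3cr1 at 3.50, each with WT well above background on 2 of 4 arrays, and Ctss at 4.00, with WT well above background on 1 of 4.

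**Figure D1:**
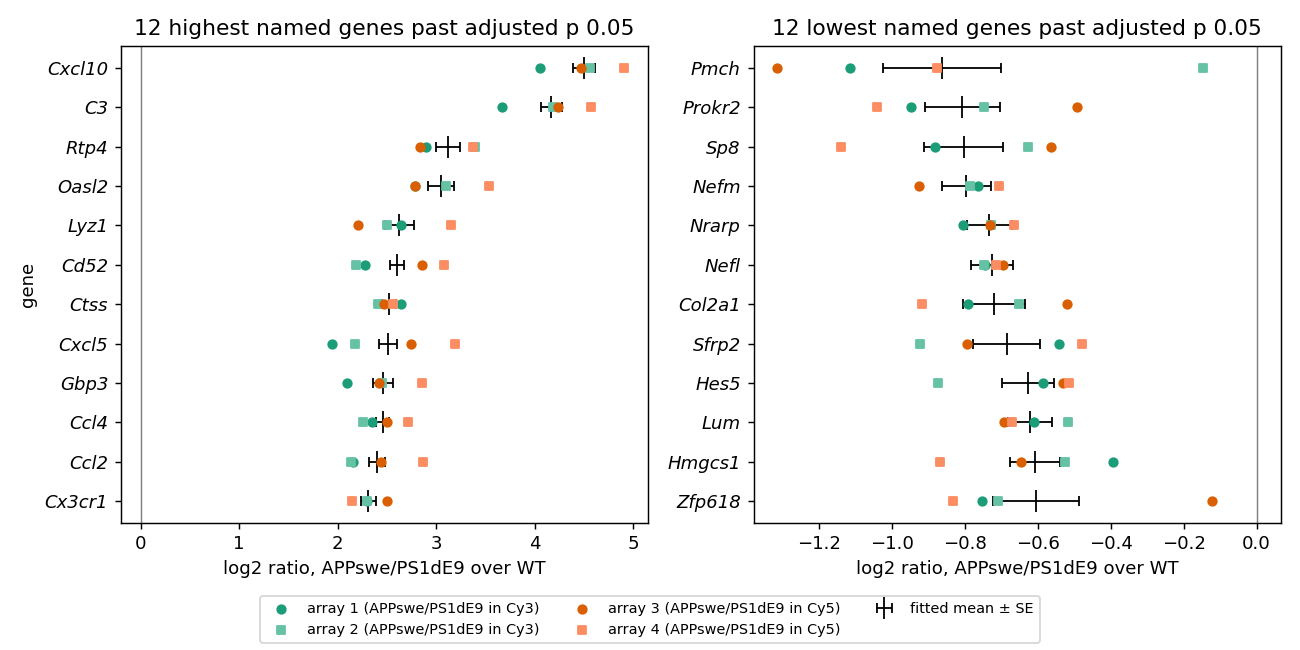
Log2 ratios (APPswe/PS1dE9 over WT, x axis) of the 12 highest and 12 lowest named genes past an adjusted p of 0.05 (y axis), with a point per array, coloured by dye orientation, and the fitted mean ± SE in black. Cxcl10 lay between 4.05 and 4.91 on the 4 arrays, while Pmch ranged from -1.31 to -0.15.

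Interferon-response genes rose as a group: 41 of 44 measured members were higher, none was lower and 3 did not pass, with a median log2 ratio of 1.18 (camera adjusted p = 1.10e-39). Adjusted p = 0.213 with an estimated correlation. Adjusted over the list alone, 44 were higher. Besides the genes above, the ubiquitin-like modifier Isg15 (2.29 ± 0.09) and the RNA-binding Ifit3 (1.74 ± 0.07) rose. The second probe of Isg15 was at 1.06 and the mean over probes at 1.68, and Feature Extraction's processed signals put the list median at 1.84. Genes of antigen presentation rose too, with 16 of 21 higher and 5 not passing (19 adjusted over the list alone), a median of 0.67 and a camera adjusted p of 2.09e-17, which became adjusted p = 0.285 with an estimated correlation. They included the MHC class I genes H2-K1 (1.76 ± 0.09), H2-T23 (1.64 ± 0.07) and H2-D1 (1.48 ± 0.09) and the immunoproteasome subunit Psmb8 (1.80 ± 0.10, and 2.96 with the processed signals, with WT well above background on 1 of 4 arrays).

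Markers of microglia and macrophages rose alongside the interferon genes. Of 32 measured, 26 were higher, 1 was lower and 5 did not pass (26 and 1 adjusted over the list alone), and the median was 1.14 (camera adjusted p = 1.17e-24; adjusted p = 0.131 with an estimated correlation). The Fc receptor subunit Fcer1g (2.23 ± 0.06), Aif1, which encodes Iba1 (2.22 ± 0.07), and C1qc (2.07 ± 0.07) were among them, and the transcription factor gene Sall1 was the member that fell (-0.30 ± 0.06). Of the genes described in disease-associated microglia, 17 of 19 were higher and 2 did not pass (17 higher and 1 lower adjusted over the list alone), with a median of 0.60 (camera adjusted p = 1.12e-14; adjusted p = 0.131 with an estimated correlation). Tyrobp (2.22 ± 0.09) and its partner receptor Trem2 (1.60 ± 0.08), Gpnmb (1.59 ± 0.06) and Lgals3 (1.05 ± 0.06) rose. Tyrobp and Trem2 stood in both lists. With Feature Extraction's processed signals Aif1 was at 2.89, Fcer1g and C1qc at 2.91, Tyrobp at 3.37, Trem2 at 2.84 and Gpnmb at 3.47, and in these last 3 genes WT was well above background on 1 of 4 arrays.

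Complement genes rose in 11 of 17 cases, with 6 not passing (12 higher and 1 lower adjusted over the list alone). Their median was 0.78 (camera adjusted p = 8.30e-09; adjusted p = 0.213 with an estimated correlation), and C4b (1.54 ± 0.08) and C1qb (1.39 ± 0.06) were among the higher. C1qa, C1qb, C1qc and Itgam of this list stood in the microglia list as well. Of the cytokine and chemokine genes, 13 of 17 were higher and 4 did not pass (14 higher and 1 lower adjusted over the list alone), with a median of 0.70 (camera adjusted p = 8.46e-11; adjusted p = 0.213 with an estimated correlation). Ccl3 was among them (2.26 ± 0.08). In the list of pattern recognition and NF-kB genes, 17 of 31 were higher and 14 did not pass (20 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 1.72e-11; adjusted p = 0.213 with an estimated correlation). The receptor genes Tlr2 (2.01 ± 0.07) and Cd14 (1.11 ± 0.07), the inhibitor Nfkbia (1.37 ± 0.07) and the subunit Relb (1.31 ± 0.08, with another probe at 0.88) rose. The processed signals put C1qb at 1.99, Ccl3 at 3.47, Tlr2 at 3.43 and Cd14 at 2.01. In Ccl3 and Cd14 WT was well above background on 2 of 4 arrays, and in Tlr2 on 1.

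Genes known from reactive astrocytes and general astrocyte markers rose. Of 32 reactive astrocyte genes, 26 were higher and 6 did not pass (29 higher and 1 lower adjusted over the list alone), with a median of 0.95 (camera adjusted p = 2.81e-23; adjusted p = 0.157 with an estimated correlation). Gbp2 rose by 2.05 ± 0.08. Of the 32 genes, 9 stood in immune lists as well, namely Cxcl10, Gbp2 and Iigp1 (interferon response), H2-T23, H2-D1 and Psmb8 (antigen presentation), C3 and Serping1 (complement) and Cd14 (pattern recognition, microglia). Of 34 astrocyte markers, 17 were higher and 17 did not pass (24 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 2.50e-09; adjusted p = 0.131 with an estimated correlation). Gfap, the intermediate filament of astrocytes (0.69 ± 0.06, with other probes at 0.42 and 1.16), Slc25a18 (1.32 ± 0.07), Mlc1 (0.75 ± 0.06) and Ntsr2 (0.58 ± 0.06) rose. Ntsr2 did not pass without replicate 3 (adjusted p = 0.0543) or replicate 4 (adjusted p = 0.0504). On the same-sex arrays neither Gfap (0.70, adjusted p = 0.0889) nor Ntsr2 (0.51, adjusted p = 0.161) passed.

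Markers of choroid plexus and ependyma, the epithelia lining the ventricles, rose in 12 of 16 cases with 4 not passing (14 adjusted over the list alone). The median was 1.07 (camera adjusted p = 1.46e-13; adjusted p = 0.131 with an estimated correlation). The cilium genes Ccdc153 (1.84 ± 0.09), Rsph1 (1.55 ± 0.07, with another probe at 0.92) and Tekt1 (1.27 ± 0.07) rose, as did the secreted chemoattractant Rarres2 (1.74 ± 0.07).

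Of 24 amyloid-processing genes, 7 were higher and 17 did not pass (8 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.000443; adjusted p = 0.330 with an estimated correlation). The lipid transporter Abca1 (1.05 ± 0.07), the apolipoprotein genes Clu (0.90 ± 0.06) and Apoe (0.60 ± 0.06), and Itm2c (0.63 ± 0.07) rose. Bace2 (0.64 ± 0.11), Itm2b (0.41 ± 0.07) and Psen2 (0.32 ± 0.06) were the other higher members. Bace1 (-0.01), Adam10 (-0.11) and Ide (0.08) were among the 17 that did not pass. Apoe stood in the list of disease-associated microglia genes as well. Apoe did not pass without replicate 4 (adjusted p = 0.0502), and on the same-sex arrays neither Apoe (0.60, adjusted p = 0.134) nor Itm2c (0.57, adjusted p = 0.130) did. Of 17 purinergic and kinin receptor genes, 7 were higher and 10 did not pass (9 higher and 1 lower adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00466; adjusted p = 0.285 with an estimated correlation). The ATP-gated channel gene P2rx7 (0.93 ± 0.07), Adora1 (0.67 ± 0.06) and Entpd2, which encodes an enzyme and not a receptor (0.56 ± 0.06), rose. P2ry6, which stood in the microglia list as well, was at 0.96 ± 0.07, with WT not well above background on any array. Its fold computed per channel was 1.92. Entpd2 did not pass without replicate 3 (adjusted p = 0.0512) or replicate 4 (adjusted p = 0.0571), or on the same-sex arrays (0.54, adjusted p = 0.126).

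Of 21 fibroblast and mural cell markers, 5 were higher, 2 were lower and 14 did not pass (11 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0227; adjusted p = 0.692 with an estimated correlation). S100a4 (1.28 ± 0.08), Thy1, which neurons also express (0.69 ± 0.07), Col5a1 (0.64 ± 0.07) and Col6a1 (0.61 ± 0.06) rose, whereas the matrix gene Lum and the receptor gene Pdgfrb (-0.45 ± 0.06) fell. The call on this list ended without replicate 2 (adjusted p = 0.0813) or replicate 4 (adjusted p = 0.0864), and Col5a1 and Col6a1 did not pass without replicate 4 (adjusted p = 0.0528 and 0.0555). On the same-sex arrays Thy1 (0.61), Col5a1 (0.71) and Col6a1 (0.65) did not pass (adjusted p = 0.0778, 0.0605 and 0.0747). Of 8 endothelial markers, 2 were higher and 6 did not pass (3 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0354; adjusted p = 0.285 with an estimated correlation). The VEGF receptor gene Flt1 was 1.32-fold higher (0.40 ± 0.07). Its APPswe/PS1dE9 signal was well above background on 3 of 4 arrays and its WT signal not on any. Egfl7 was higher (0.30 ± 0.07, adjusted p = 0.04998), and Slco1a4 (0.26 ± 0.08) and Ramp2 (0.14 ± 0.06) did not pass, although Slco1a4 did without replicate 1 (adjusted p = 0.0298). Egfl7 lost its call under 10 of 13 processing alternatives (adjusted p up to 0.259), and Flt1 lost it in 1 (adjusted p = 0.0653). The endothelial call ended under 5 of 13 processing alternatives (adjusted p up to 0.367), without replicate 2 (adjusted p = 0.274) and without replicate 3 (adjusted p = 0.0875), and neither gene passed without replicate 3 (0.111 for Flt1, 0.130 for Egfl7) or replicate 4 (0.0744 and 0.198), or on the same-sex arrays (0.340 and 0.414). Egfl7 did not pass without replicate 1 either (adjusted p = 0.116). The log2 ratios on the same-sex arrays were 0.34 for Flt1 and 0.30 for Egfl7.

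Cholesterol synthesis genes fell, the list that was lower in APPswe/PS1dE9 cultures. Of 24 measured, 16 were lower, none was higher and 8 did not pass (19 lower adjusted over the list alone), with a median of -0.36 (camera adjusted p = 2.40e-14; adjusted p = 0.157 with an estimated correlation). Hmgcs1, which makes HMG-CoA (-0.61 ± 0.07), the sterol carrier gene Stard4 (-0.59 ± 0.06), the isomerase gene Idi1 (-0.59 ± 0.06) and the demethylase gene Cyp51 (-0.59 ± 0.06) fell on 4 of 4 arrays. Without replicate 4 these 4 genes had adjusted p between 0.0506 and 0.0627, while the list kept its call with a median of -0.34. Without replicate 3, Idi1 and Stard4 did not pass (adjusted p = 0.0512 and 0.0533), and on the same-sex arrays none of the 4 did (adjusted p between 0.0590 and 0.139). Their log2 ratios there were -0.70 for Hmgcs1, -0.64 for Idi1, -0.56 for Cyp51 and -0.55 for Stard4.

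The lowest named genes otherwise included the neuropeptide gene Pmch (-0.86 ± 0.16), Prokr2 (-0.81 ± 0.10), the transcription factor gene Sp8 (-0.80 ± 0.11, with a second probe at -0.24 that did not pass, adjusted p = 0.0662) and the neurofilament genes Nefm (-0.80 ± 0.07) and Nefl (-0.72 ± 0.06). The Notch-related genes Nrarp (-0.73 ± 0.06) and Hes5 (-0.63 ± 0.07), the matrix genes Col2a1 (-0.72 ± 0.08) and Lum (-0.62 ± 0.06), the Wnt modulator Sfrp2 (-0.68 ± 0.09) and Zfp618 (-0.60 ± 0.12) were the others. Without replicate 4, 9 of the 12 lowest did not pass (adjusted p between 0.0502 and 0.136), and Nefm, Nrarp and Nefl did. Without replicate 3, Pmch, Sfrp2 and Hes5 did not (adjusted p between 0.0668 and 0.184). On the same-sex arrays Pmch (-0.51), Sfrp2 (-0.70), Hes5 (-0.69), Lum (-0.59) and Hmgcs1 (-0.70) did not (adjusted p between 0.0637 and 0.310). With Feature Extraction's processed signals Nrarp was at -2.03, Lum at -1.74 and Pmch at -2.95, where Pmch did not pass (adjusted p = 0.0580). APPswe/PS1dE9 was well above background on 2 of 4 arrays for Nrarp and on 1 for Lum and Pmch. Pmch lost its call under 4 of 12 processing alternatives and Zfp618 under 3 of 13 (adjusted p up to 0.0889 and 0.0916).

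**Figure D2:**
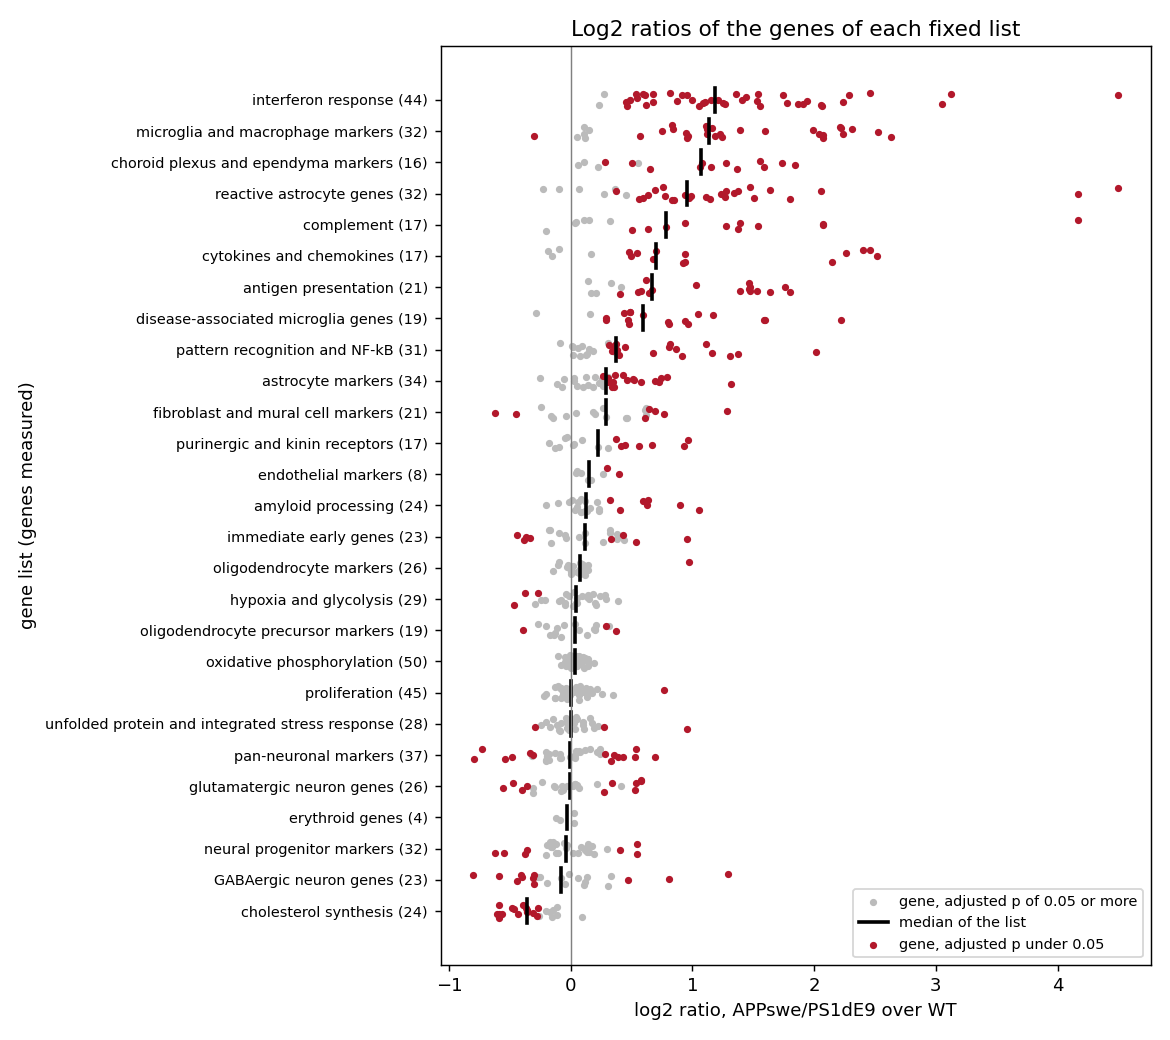
Log2 ratios (APPswe/PS1dE9 over WT, x axis) of the measured genes of the 27 tested lists (y axis, number of genes in brackets), with genes past an adjusted p of 0.05 in red and list medians as black bars. List medians ran from -0.36 for cholesterol synthesis to 1.18 for the interferon response.

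Neuronal lists moved in both directions and did not pass. Of 37 pan-neuronal markers, 8 were higher, 6 lower and 23 did not pass (11 and 11 adjusted over the list alone; camera adjusted p = 0.467), though under median centring the list passed as lower (median -0.15, adjusted p = 0.0223). The immature neuron gene Dcx (-0.54 ± 0.11) fell with Nefm and Nefl, while the synaptic vesicle genes Syt1 (0.43 ± 0.10) and Syp (0.35 ± 0.08) rose. Of 23 GABAergic genes, 3 were higher, 8 lower and 12 did not pass (5 and 10 adjusted over the list alone; camera adjusted p = 0.0904). The homeobox genes Dlx1 (-0.59 ± 0.08) and Dlx5 (-0.44 ± 0.07) fell, and the neuropeptide genes Npy (1.29 ± 0.06) and Sst (0.81 ± 0.07) rose. The GABAergic list passed as lower without replicate 3 (median -0.21, adjusted p = 0.0109), without the dye term (adjusted p = 0.0380) and on the same-sex arrays (median -0.15, adjusted p = 0.0210). Of 26 glutamatergic genes, 6 were higher, 4 lower and 16 did not pass (8 and 6 adjusted over the list alone; camera adjusted p = 0.579). Tbr1 (0.53 ± 0.07) and Slc17a7 (0.58 ± 0.06) rose, and Neurod2 (-0.48 ± 0.07) fell. Of 32 neural progenitor markers, 3 were higher, 4 lower and 25 did not pass (3 and 4 adjusted over the list alone; camera adjusted p = 0.266). Gsx2 fell (-0.55 ± 0.07) and Hopx rose (0.54 ± 0.06).

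The other lists did not pass either. Of 19 oligodendrocyte precursor markers, 2 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.879), and their median was 0.04 where camera, on the 18 with values on all arrays, gave a lower direction. Of 26 oligodendrocyte markers 1 was higher, the transferrin gene Trf (0.97 ± 0.06; 1 adjusted over the list alone; camera adjusted p = 0.402). Of 45 proliferation genes 1 was higher, Ccnd1 (0.77 ± 0.12; 1 adjusted over the list alone; camera adjusted p = 0.879). The proliferation list passed in opposite directions when different arrays were left out, with a median of 0.12 without replicate 3, 0.19 on the same-sex arrays, and medians of -0.07 and -0.08 without replicates 2 and 4. Of 28 genes of the unfolded protein and integrated stress response, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.945), and of 29 hypoxia and glycolysis genes 3 were lower (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.945). Of 23 immediate early genes, 4 were higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.679), with Atf3 at 0.95 ± 0.08 and Egr1 at -0.44 ± 0.08. In limma, 0 of 50 oxidative phosphorylation genes passed, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.534). The median of that list, 0.03, passed with Feature Extraction's processed signals (0.03, adjusted p = 0.0205) and turned to -0.15 under median centring (adjusted p = 0.0398). Without replicate 3 the oligodendrocyte and oxidative phosphorylation lists passed, with medians of 0.13 and 0.07. For 4 erythroid genes the counts in limma were 0, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.558). Of the sex-linked list 1 gene, Xist, was kept, and it did not pass (-0.02 on average, with either genotype well above background on 3 of 4 arrays).

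Of the loci linked to the transgenes, App was at 0.12 ± 0.06 (adjusted p = 0.281) and did not pass. Prnp, whose promoter drives the transgenes of this mouse line, was at 0.75 ± 0.20 (adjusted p = 0.0659), with 1.57 on replicate 3 and 0.25 to 0.59 on the other arrays. It passed without replicate 1, 2 or 4 (adjusted p = 0.0226, 0.0265 and 0.0205) and under median centring (0.57), the filter on both channels (adjusted p = 0.0492) and the robust variance model with a trend (adjusted p = 0.0437), and without replicate 3 it was at 0.42. Adjusted over this list alone, 1 of the 2 measured genes was higher. Whether these probes detect the transgene transcripts is not given in the sources used here. Among classical markers of neural cell types, the progenitor filament gene Nes was higher (0.55 ± 0.13, adjusted p = 0.0468). Nes did not pass without replicate 3 (adjusted p = 0.209) or replicate 4 (adjusted p = 0.223), nor under 7 of 13 processing alternatives (adjusted p up to 0.138). With a covariate for sex-linked signal Nes stayed at 0.55 and did not pass (adjusted p = 0.0569). The neuronal tubulin gene Tubb3 was at -0.13 ± 0.08, the myelin gene Mbp at 0.09 ± 0.07 (another probe at -0.13) and the proliferation marker Mki67 at 0.05 ± 0.11, and these 3 did not pass. Median centring without loess gave Tubb3 -0.33 (adjusted p = 0.0453) and turned the signs of App (-0.06), Mbp (-0.04) and Mki67 (-0.09).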

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

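The tests of this part were chosen before the results were seen. Among 105 sets of 4 array values, 3 had an array standing apart from the rest, where chance gives about 5.2. C1qb was at 1.47 on replicate 1 and between 1.36 and 1.37 on the other arrays. Trem2 was at 1.91 on replicate 1 and between 1.46 and 1.54 elsewhere. The cilium gene Ccdc153 was at 1.47 on replicate 2 and between 1.93 and 2.00 elsewhere. All 3 genes were higher in APPswe/PS1dE9 on each array.

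With 4 arrays and a dye term, 7 assignments of signs to the arrays could be fitted, too few for a share under 0.05. The real assignment gave 1698 features higher and 470 lower, and the highest count of the others was 0 in either direction, so 1 of 7 gave as many in each case. For gene lists the real assignment gave 14 higher and 1 lower. Taking the larger direction of each other assignment, the highest was 15 lists, and 3 of 7 reached 14 and 7 of 7 reached 1. These are not null groupings, since assignments that set 1 array against 3 still carry part of the genotype difference. The assignments that split each dye orientation carry none of it and gave 1 list higher and 3 lower, and 2 higher and 1 lower. All other assignments leave genotype difference in the residual spread, which lowers their gene counts.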

How the results depend on the processing

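The alternatives by sex of the cultures were chosen after seeing the data, and the block by slide or scan was not run because the arrays shared 1 slide and 1 scan. Each value is already a ratio between the paired genotypes of 1 array. Of 71 named genes past the threshold, 66 stayed past it under each processing alternative that gave them a value, and 51 without each array in turn. No gene past the threshold both as reported and under an alternative changed sign. Features higher and lower numbered 719 and 240 with Feature Extraction's processed signals, 720 and 239 with the deposited value table, 960 and 103 with no filter on dim probes, and 469 and 11 on same-sex arrays only, where the dye term was left out because 2 arrays cannot carry it, so that these counts differ in the model as well as in the arrays. Features lower numbered 259 with no dye term, 284 with no background correction and 1307 with median centring (50% of calls higher, against 78.3%). A filter asking for both channels on all arrays gave 1529 and 609. Leaving out an array gave 368 to 2242 higher and 4 to 513 lower, on 1 residual degree of freedom. Lists lower numbered 2 with no dye term, 3 with median centring, 2 on same-sex arrays and 1 to 2 without an array. With an estimated correlation 0 lists were higher and 0 lower in camera, and 6 had an unadjusted p under 0.05. That setting rests on 2 residual degrees of freedom, so the loss of calls does not by itself show an effect of gene correlation. Astrocyte markers and disease-associated microglia genes had estimated correlations of -0.010 and 0.0059, under the preset 0.01. Both lost their calls there all the same (camera adjusted p = 0.131). fry called 13 lists, without the fibroblast and endothelial lists. Results that had not passed changed sign, for lists together with the direction of the set test, as follows. Median centring gave App -0.061, Mbp -0.041, Mki67 -0.092, oligodendrocyte markers -0.074 and oxidative phosphorylation -0.15. The mean over probes gave Mbp -0.018. Proliferation, at 0.0063 with a lower direction in the set test as reported, was at -0.031 with the processed signals and -0.0306 with the value table. On same-sex arrays its median kept its sign (0.19) and the direction of the test turned to higher, where it passed. Without an array, Mki67 ran from -0.096 to 0.20, proliferation from -0.084 to 0.12, oligodendrocyte markers from -0.0042 to 0.13, glutamatergic genes from -0.046 to 0.030 and oxidative phosphorylation from -0.0034 to 0.066. The gene list oligodendrocyte precursor markers had a median of -0.0093 over the 18 genes with values on all arrays and 0.038 over 19. It was 0.014 with the mean over probes and 0.038 with every probe tested, with the direction of the test turned to higher. Other medians near 0 crossed it as well. Without an array these were pan-neuronal markers (-0.056 to 0.035), erythroid genes (-0.098 to 0.0034), immediate early genes (-0.00031 to 0.15), the unfolded protein and integrated stress response (-0.0095 to 0.0091) and oligodendrocyte precursors (-0.026 to 0.045). Median centring gave proliferation -0.10 and hypoxia and glycolysis -0.099, no background correction gave glutamatergic genes 0.030 and proliferation a median just under 0, every probe tested gave proliferation -0.016, and oligodendrocyte precursors were at 0.011 with no filter and 0.019 on same-sex arrays. The cause was not tested. Signal over background limits dim genes, whose ratios shrink with the offset.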

Other observations

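The tests of a larger microglial share, of dye bias and of dilution, and the 4 gene lists named here, were chosen after the first results were seen. Motile cilium genes outside the ependymal list rose, with 28 of 35 measured higher, none lower and a median of 0.62, among them the axonemal genes Cfap52 (1.37 ± 0.06) and Dnah6 (1.19 ± 0.08). Lysosome genes rose in 14 of 32 cases, with Ctsh at 1.74 ± 0.06, Ctsc at 0.92 ± 0.10 and a median of 0.25. Targets of LXR, the nuclear receptor of sterol efflux, rose in 7 of 13 cases, with Abcg1 at 1.59 ± 0.07 and Pltp at 0.88 ± 0.06, and 1, Eepd1, fell (-0.39 ± 0.06). With an estimated correlation the adjusted p of these lists were 0.110, 0.106 and 0.106.

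Cultures differed in sex-linked signals. On replicate 1 the Y-linked gene Eif2s3y was well above background in the APPswe/PS1dE9 culture alone and Xist in the WT culture alone, and on replicate 3 it was the other way round. On replicates 2 and 4 Eif2s3y was not well above background in either culture and Xist was in both, with log2 ratios of -0.41 and -0.22. The Y-linked gene Ddx3y, however, was well above background in both cultures on replicate 2, where its signal was left out as an outlier. Calling these arrays same-sex therefore rests on Eif2s3y and Xist. With the Eif2s3y ratio as a covariate beside genotype and dye, on 1 residual degree of freedom and with 1 or both channels of that ratio not well above background on each array, 1552 features were higher and 373 lower.

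Of 2260 features that the array names by a genomic interval (mm9), 41 were higher and 30 lower. The highest was on chromosome 8, 93337794 to 93348869, reverse strand (1.48 ± 0.07), and the lowest on chromosome 10, 96103732 to 96103867, forward strand (-1.04 ± 0.09). They were chosen after their values were seen, and what they overlap was not analysed here.

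Interferon-response and microglial genes were higher together. Gene-specific dye bias that is alike on all arrays goes into the dye intercept, so the balanced design keeps it out of the genotype coefficient. Of the 76 measured genes of both lists, 96.1% had the same sign in both dye orientations. Most of these genes had passed the threshold, which all but requires a common sign, so this share adds no separate evidence. A larger share of microglia alone stays open. Replicates 4 and 1 were compared because the interferon median differed most between them, and microglial genes differed by 0.057 there and by 0.33 less than interferon genes (95% bootstrap interval 0.13 to 0.49). The choice of arrays fixes a large interferon change, and 1 array is set against 1 of the other dye orientation, so these values decide nothing about the share. A change of state in microglia or other cells, and differences between litters or cultures, may also contribute and were not tested.

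Cholesterol synthesis genes were lower. Intensity-dependent bias would give such a median in intensity-matched random lists, and 0% of 10000 lists were as low. Loess had already removed trends with intensity within each array, so random lists lay near 0 (median 0.006) and the outcome was largely fixed. It shows only that genes of like intensity did not share the fall after loess, and decides nothing about intensity bias before it. Dilution by other cells would lower other neural genes alike, but the list lay -0.45 from the pooled pan-neuronal, astrocyte and progenitor markers (95% bootstrap interval -0.55 to -0.31). The pool holds the astrocyte markers, which had risen (median 0.29) and widen this difference. Pan-neuronal and progenitor medians were -0.0036 and -0.036, against -0.36 for cholesterol synthesis. The interval covers the spread of genes, not of cultures, so dilution is not excluded. LXR targets had a median of 0.41 (camera adjusted p = 0.000105; adjusted p = 0.106 with an estimated correlation), which is consistent with the hypothesis of a response to sterol load. Microglial markers rose as well (median 1.14), so LXR targets from microglia stay open, as do culture differences, and sterol content was not measured.

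Ependymal genes were higher. A single array deciding this would bring the median to 0 without it, and the lowest median with an array left out was 0.95. The motile cilium list, at a median of 0.62 (camera adjusted p = 5.14e-21; adjusted p = 0.110 with an estimated correlation), was higher too, which is consistent with the hypothesis of more ciliated cells. Whether this reflects genotype or the tissue that entered the cultures at dissection was not tested.

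A hypothesis of lower Notch signalling came from Hes5, Nrarp and Dll1. In 14 other Notch pathway genes the median was -0.057 (camera adjusted p = 0.0362), 1 gene, Mfng, fell (-0.51 ± 0.06), and adjusted p = 0.156 with an estimated correlation, so the shift was small and rested on few genes. A rise of lysosomal genes, a hypothesis from the cathepsin genes, was in line with the median of 0.25 in the lysosome list (camera adjusted p = 6.54e-08; adjusted p = 0.106 with an estimated correlation). Microglial markers rose with these genes (26 of 32 higher, median 1.14), so a larger share of microglia stays open here too.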
